A study of Mus musculus with 3 samples.

How the data were processed

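Gene expression was measured in 3 samples of mouse CD8 T cells, 1 without added cholesterol and 1 each at 0.5 and 0.75 µg/ml, with 1 array per sample. Per the labels, total RNA was extracted with Trizol and labelled with biotin by a whole-transcript sense protocol. The deposited table holds 1 intensity per probe set and array on a linear scale, per the values themselves. The software, background correction and normalization that the authors used are not given in the sources used here, and the near-identical distributions of the 3 arrays leave no sign of a remaining overall scale difference. The labels do not say how many animals or cultures the cells came from. They also do not give how long cholesterol was present or its carrier, so an effect of the carrier cannot be told apart from one of cholesterol.

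The table holds 28846 probe sets. Of 22206 transcript probe sets, 19572 had 1 gene symbol in the platform annotation, 0 had several and 2634 are unnamed here. All 19572 gene identifiers matched a reference gene table of the assembly GRCm38.p6, with 0 differing symbols. The remaining probe sets were 5222 negative controls, 1324 positive controls and 94 spike-in or background controls, which stayed out of all gene counts. Log2 was taken after a floor of 1, which 0 values fell under, and no further normalization was applied. For the 55 genes with more than 1 probe set the brightest by mean over the arrays was used, which left 19505 genes. Genes were kept if their mean log2 value reached the median over all probe sets, 5.02 or an intensity of 32.4, which 10940 did. That filter also let through 19.8% of negative and 88.0% of positive controls, so kept genes include dim ones. For a gene with 1 array under the highest 95th percentile of the negative controls, 102, a lower bound of the fold was computed with the dim value raised to it. Some genes that the naming rule lists are not reported here.

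Each of the 3 comparisons is a difference of log2 values between 2 arrays. A gene was counted if it differed at least 2-fold. With 1 array per group there is no test and no replicate check. Of 28 gene lists the median difference was computed over all measured members, and its percentile among 10000 random lists of the same size matched on mean level in 20 bins. A list stood apart if the percentile was under 2.5 or over 97.5. These percentiles ignore the correlation between genes and describe these arrays only. The error given for a list median is the 95% interval from the order statistics of its members.

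The lists were sterol synthesis and uptake, LXR targets and efflux, fatty acid synthesis, chaperones and degradation factors of the endoplasmic reticulum, ATF4 and CHOP targets, inhibitory receptors and exhaustion-linked regulators, and cytotoxic effectors and Tc1 cytokines. Further lists held naive and memory T cell genes, type 2, type 9 and type 17 genes, activation and immediate-early genes, the T cell receptor complex, mitosis and G2/M, DNA replication and G1/S, glycolysis and hypoxia, mitochondrial respiration, fatty acid oxidation and lipid storage, interferon-stimulated genes, p53 targets, NRF2 targets and ferroptosis, heat shock, ribosomal proteins, and homing and tissue residence. The other 6 held markers of B cells, of macrophages, dendritic cells and monocytes, of CD4 T cells, of NK and gamma-delta T cells, of neutrophils and mast cells, and of erythroid cells and platelets. The groups, the comparisons, these lists, the threshold, the level filter, the naming rule and all but 2 of the alternatives were chosen before the data were examined. Added later were 3 lists of further interferon-stimulated, interferon-gamma-inducible and hypoxia-inducible genes, picked before the values of their members were read.

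Genes were named by rule. It took the 10 highest and 10 lowest kept genes at each dose against the control, the 10 highest and lowest by the smaller difference among those on the same side at both doses, the 5 highest and lowest between doses, and up to 4 members of each list with the largest mean difference. A fixed set, such as Hmgcs1, Abca1, Pdcd1, Ifng and Cd8a, was named whatever its values. Predicted and clone-named genes, small RNA genes, olfactory receptors and antigen receptor segments were counted but not named, and exceptions are marked in the text.

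Because both doses share 1 control array, overlaps and correlations between them were set beside 100 simulations of unchanged arrays with noise taken per level bin from the difference between the doses. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9. The steps were tested on simulated data for the 0.75 µg/ml comparison with the control over 10940 genes. The noise was normal, scaled per level bin by the median absolute deviation of the difference between the doses. All 100 genes changed 4-fold and all 100 changed 2.83-fold were counted, and 0 of 10740 unchanged genes passed 2-fold. Such noise leaves out outlying probe sets, so that 0 does not estimate the share of false calls. On the real arrays 1.12% of positive controls past the filter differed at least 2-fold between 0.75 µg/ml and the control. Of 300 unchanged lists 14 fell outside the middle 95%, and 100 of 100 lists of 20 genes lowered by 0.5 were found. Those lists were random genes with independent noise, so the 14 does not give the share for real lists of correlated genes. Alternatives tried were quantile normalization, median centring, removal of a lowess trend with level (fraction 0.3), the mean of a gene's probe sets, no level filter, only the brightest genes (the top 33.3% by level), a 1.5-fold threshold, the mean of list members, list members past the filter only, and random lists matched on the control array. The other alternatives, chosen after seeing the data, were the background floor at 102 and the smaller noise in the shared-control simulation.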

Results

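Mouse CD8 T cells stimulated through CD3 and CD28 were cultured with Tc1 cytokines, which drive CD8 T cells toward cytotoxic effectors that make interferon-gamma. The cells received no added cholesterol (control), 0.5 µg/ml cholesterol or 0.75 µg/ml cholesterol, and total RNA was hybridised to whole-transcript expression arrays. Each condition had 1 array, so none of the differences below has a replicate check, no p-values are given, and the number of arrays limits the precision of every value. The 3 arrays had near-identical overall levels, with median intensities of 32.5 for the control, 32.4 at 0.5 µg/ml and 33.0 at 0.75 µg/ml. The lineage genes Cd8a, at 4225, 4164 and 3313 in that order, and Cd3e, at 4364, 4650.1 and 4594, were bright on all 3 arrays, as was the granzyme gene Gzmb at 7611, 7741 and 8136. Of 19505 genes, 10940 passed the level filter. Negative-control probe sets had a 95th percentile of 102 or lower on each array, and a gene with all its values under that level is described by its intensities without a fold.

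The first comparison asked what 0.5 µg/ml cholesterol changed in the cells' transcripts. Genes of sterol synthesis were lower and the cholesterol exporter gene Abcg1 was higher than in the control. Of the 19 measured sterol synthesis and uptake genes, which the transcription factor SREBP2 drives, 18 were below the control, with a median log2 difference of -0.51 (95% interval over members -0.64 to -0.37). Squalene epoxidase (Sqle) was at 247 against 482, mevalonate diphosphate decarboxylase (Mvd) differed by -0.99 and the sterol oxidase Msmo1 by -0.71 on the log2 scale. Abcg1 was 2.08-fold higher, at 280 against 135, and the exporter gene Abca1 was at 32.6 against 16.5, under the background level on both arrays.

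In all, 10 genes were at least 2-fold higher and 6 at least 2-fold lower at 0.5 µg/ml. Among them, Klrd1 differed by 1.10, and Klrc1, whose product pairs with that of Klrd1 into an inhibitory receptor for non-classical MHC molecules, was at 121 against 50.3, at least 1.19-fold higher over the background level. The transglutaminase gene Tgm2 was lower, at 276 against 709. Havcr2, which encodes the inhibitory receptor TIM-3, was at 39.5 against 18.8, with every array under the negative controls' 95th percentile. The same held for the lower genes Fscn1, at 30.8 against 90.7, Galc, at 30.4 against 64.9, Papss2, at 29.8 against 61.4, and Plxnb3, at 20.8 against 49.5. When all values under 102 were raised to that level, 2 genes were still at least 2-fold higher, Klrd1 and Abcg1, and 1 gene lower, Tgm2.

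Of the 28 gene lists, 5 had a median above and 5 a median below the middle 95% of level-matched random lists at this dose. The sterol list lay below all 10000 random lists. Fatty acid synthesis genes had a median of -0.12, with Fads2 at -0.61 and Fads1, another fatty acid desaturase, at -0.35. Interferon-stimulated genes had a median of -0.16, or 0.00 with values under 102 raised to that level, and 1 random list was lower than -0.16, with Stat2, part of the type I interferon signalling complex, at -0.58. The p53 target list (-0.15) and the ribosomal protein list (-0.02) were low as well. Targets of the oxysterol receptor LXR had a median of 0.18 (95% interval -0.13 to 0.51), higher than in 99.5% of random lists, and included the ubiquitin ligase gene Mylip at 134 against 94.0. Only 7 of the 13 measured LXR targets were above the background level on the control array, and the LXR median was 0.00 with values under 102 raised to that level. The other high lists were the ATF4 and CHOP targets (0.10, or 0.04 with dim values raised), the cytotoxic effectors and Tc1 cytokines (0.10, or 0.00 likewise), mitosis and G2/M (0.10), and glycolysis and hypoxia (0.09). Positive-control probe sets past the filter had an SD of 0.30 between these 2 arrays against 0.21 for genes, and 8 of 1165 (0.687%) differed at least 2-fold against 0.146% of genes.

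The second comparison addressed 0.75 µg/ml cholesterol against the control. Sterol synthesis genes were lower by far more than at 0.5 µg/ml, Abca1 and Abcg1 were higher, and interferon-stimulated, hypoxia-inducible and naive or memory T cell genes were lower as groups. The genes at least 2-fold different numbered 211, of which 172 were lower and 39 higher. Of the 28 lists, 7 had a median above and 10 a median below the middle 95% of random lists. The sterol list had a median of -1.68 (95% interval -2.33 to -1.29), below all random lists, and 18 of its 19 members were at least 2-fold lower. Hmgcs1, which makes HMG-CoA for sterol synthesis, was at 285 against 1848, Insig1, a sterol-regulated retention factor for SREBP, differed by -2.14, and the gene for SREBP2 itself, Srebf2, by -1.22. Sqle was at 80.7 against 482 and the farnesyl diphosphate synthase gene Fdps at 62.1 against 383, which is at least 4.74-fold and at least 3.76-fold lower when the dim value is raised to the negative controls' 95th percentile. The exception was Ebp, chosen after its value was seen, at 0.01.

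Among the other lipid genes, Abcg1 was 3.20-fold higher, at 431 against 135, and Abca1 was at 162 against 16.5, or at least 1.60-fold higher over the background level. The LXR list had a median of 0.20 (95% interval -0.67 to 0.87), above 98.9% of random lists, with 8 members above and 5 below the control, and a median of 0.00 with values under 102 raised to that level. Npc2, which moves cholesterol out of lysosomes, was a low member at -1.36. Rxra, which encodes the retinoid X receptor that LXR binds as a partner, was at 172 against 36.0, at least 1.69-fold higher over the background level. Fatty acid synthesis genes had a median of -0.34 (95% interval -0.78 to -0.05), below all random lists. The desaturase gene Fads2 was at 72.4 against 1548, at least 15.2-fold lower against the background level, and the elongase gene Elovl6 differed by -1.24. The fatty acid oxidation and lipid storage list had a median of -0.07 and lay within the middle 95% of random lists.

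Interferon-stimulated genes had a median of -0.97 (95% interval -1.58 to -0.80) at 0.75 µg/ml, below all random lists. Of 23 measured members, 22 were below the control and 11 were at least 2-fold lower. The transcription factor genes Irf7, at 95.7 against 507, and Stat2, at 289 against 867, were among them, as was the antiviral gene Ifit3 at 56.4 against 242. The related gene Ifit3b was at 27.1 against 174, and copies in this family are similar in sequence. The interferon-gamma gene Ifng itself was at 294 against 333. Several members were dim at 0.75 µg/ml, and the list's median was -0.49 with values under 102 raised to that level.

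Hypoxia and glycolysis genes had a median of -0.30 (95% interval -0.67 to -0.24), below all random lists, with 22 of 23 members below the control. The aldolase gene Aldoc was at 51.2 against 688, at least 6.76-fold lower against the background level. The glucose transporter gene Slc2a3 differed by -1.69 and the oxygen-sensing prolyl hydroxylase gene Egln3 by -1.44, and the angiogenic factor gene Vegfa was at 46.4 against 168, at least 1.65-fold lower. Nuclear-encoded mitochondrial respiration genes had a median of 0.12, above 97.6% of random lists, with Ndufa4 at 0.43.

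Naive and memory T cell genes had a median of -0.36 (95% interval -0.55 to -0.11), below all random lists, and 20 of 21 members were below the control. Klf2, which maintains T cell quiescence and recirculation, was at 51.4 against 223 and Klf3 at 44.3 against 149, at least 2.20-fold and at least 1.46-fold lower against the background level, and the kinase gene Txk differed by -1.45. P-selectin (Selp) was at 164 against 999 and Tgm2 at 81.2 against 709. Homing and tissue residence genes had a median of -0.17, under the 2.5th percentile, or -0.01 with values under 102 raised to that level, with Gpr183, a receptor for oxysterols, at -0.95 and Ccr2 at 62.6 against 17.8, under the background level on both arrays.

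Inhibitory receptors and exhaustion-linked regulators had a median of -0.14 (95% interval -0.48 to 0.08) at 0.75 µg/ml, under the 2.5th percentile of random lists, or -0.02 with values under 102 raised to that level, with members in both directions. The checkpoint gene Ctla4 was 3.33-fold lower, at 335 against 1115, Lag3 was 2.39-fold lower, at 123 against 294, and the regulators Ikzf2 and Tox differed by -1.26 and -0.65. Pdcd1, which encodes PD-1, was at 154 against 165, and Tigit at 172 against 209. Havcr2 was at 75.5 against 18.8, under the background level on both arrays, and so was Cd244a, at 21.7 against 20.7.

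Cytotoxic effectors and Tc1 cytokines had a median of 0.10 (95% interval -0.31 to 0.40), within the middle 95% of random lists. The median was 0.00 with values under 102 raised to that level, and members of this list also went both ways. Csf2, the gene of the growth factor GM-CSF, was at 170 against 36.4, at least 1.67-fold higher over the background level, and the chemokine gene Ccl3 was at 143 against 58.7, under the background level on the control array. The chemokine receptor gene Cxcr3 differed by 0.81 and the interleukin-12 receptor gene Il12rb2 was at 1382 against 2766. Perforin (Prf1) was at 93.9 against 129, Tnf at 1065 against 856, and the Tc1 regulators Tbx21 and Eomes differed by -0.08 and 0.53. Type 2, type 9 and type 17 genes had a median of 0.22, above 99.8% of random lists, but only 8 of the 22 passed the level filter and 5 were above the background level on the control array. With values under 102 raised to that level the median of the type 2, type 9 and type 17 list was 0.00. Its most different members, Ccr8 at 53.3 against 12.9 and Maf at 37.7 against 14.3, were under the background level, as were Il9 and Il2.

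Chaperones and degradation factors of the endoplasmic reticulum had a median of 0.25 (95% interval 0.10 to 0.41) at 0.75 µg/ml, above all 10000 random lists, and none of the 24 members differed 2-fold. The chaperone genes Hyou1, Sdf2l1 and Hspa5 differed by 0.69, 0.70 and 0.37, and Xbp1, a transcription factor that drives the unfolded protein response, by 0.32. The ATF4 and CHOP target list had a median of -0.01, within the middle 95% of random lists, with Atf4 at 0.13 and Ddit3, the gene for CHOP, at -0.22. The other stress lists were high, the NRF2 targets and ferroptosis genes with a median of 0.15 and Gclm at 0.81, the heat shock genes with 0.20 and Hsph1 at 0.80, and the p53 targets with 0.13 and Perp at 1.02. With values under 102 raised to that level, the medians of the NRF2, heat shock and p53 lists were 0.02, 0.00 and 0.07.

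Ribosomal protein genes had a median of -0.18 at 0.75 µg/ml, and 2 of the 10000 random lists were lower. Immediate-early and activation genes (-0.03), the T cell receptor complex (0.00), mitosis and G2/M (0.10) and DNA replication (0.12) lay within the middle 95%, although DNA replication, at the 97.3rd percentile, was at the 98.5th among random lists matched on the control array. Of the activation genes 12 were above and 14 below the control. Members differed both ways, with Egr3 and Cd44, chosen after their values were seen, at 0.80 and 0.71, the costimulatory receptor gene Tnfrsf9 at 1636 against 3625 and the NF-kappaB inhibitor gene Tnfaip3 at -1.20, while the proliferation marker Mki67 differed by 0.04. The genes with the highest differences included the actin-binding protein gene Rai14, at 322 against 51.4, and Jcad, at 216 against 67.0, at least 3.16-fold and at least 2.12-fold higher over the background level. The galectin gene Lgals3 was high at both doses, at 209 and 273 against 106.

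Marker genes of other cell types were mostly dim. At 0.75 µg/ml the B cell list had a median of -0.18 and the CD4 T cell list one of -0.56, both under the 2.5th percentile of random lists. Only 4 of the 12 B cell markers passed the level filter, with a median of 0.08, and 2 were above the background level on the control array. Cd4 itself was at 61.6, 39.4 and 35.7 across the control and the rising doses, under the background level, and the CD4 list shares Ctla4 with the inhibitory receptors and Tnfrsf4, named after its value was seen because its difference of -0.56 is the list's median, with the activation genes. The macrophage, dendritic cell and monocyte list (-0.06), the NK and gamma-delta T cell list (0.13), the neutrophil and mast cell list (0.05) and the erythroid and platelet list (-0.10) lay within the middle 95%. The 5 macrophage, dendritic cell and monocyte markers past the level filter had a median of -0.41. Only 2 of the 14 neutrophil and mast cell markers passed the level filter, with a median of -0.79, and 1 of them, Kit, was at 42.4 against 133, under the background level at 0.75 µg/ml. With values under 102 raised to that level the medians of the B cell list, the CD4 T cell list and the neutrophil and mast cell list were 0.00. The MHC class II gene H2-Ab1, which is bright in antigen-presenting cells, was at 83.4 against 266, so it was lower together with the interferon-stimulated genes. H2-Eb1, another class II gene, was at 99.1 against 153, and was already at 103 at 0.5 µg/ml. Positive-control probe sets had an SD of 0.31 between these 2 arrays against 0.36 for genes, and 13 of them (1.12%) differed at least 2-fold against 1.93% of genes. Raising values under 102 to that level left 15 genes higher and 98 lower.

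**Figure D1:**
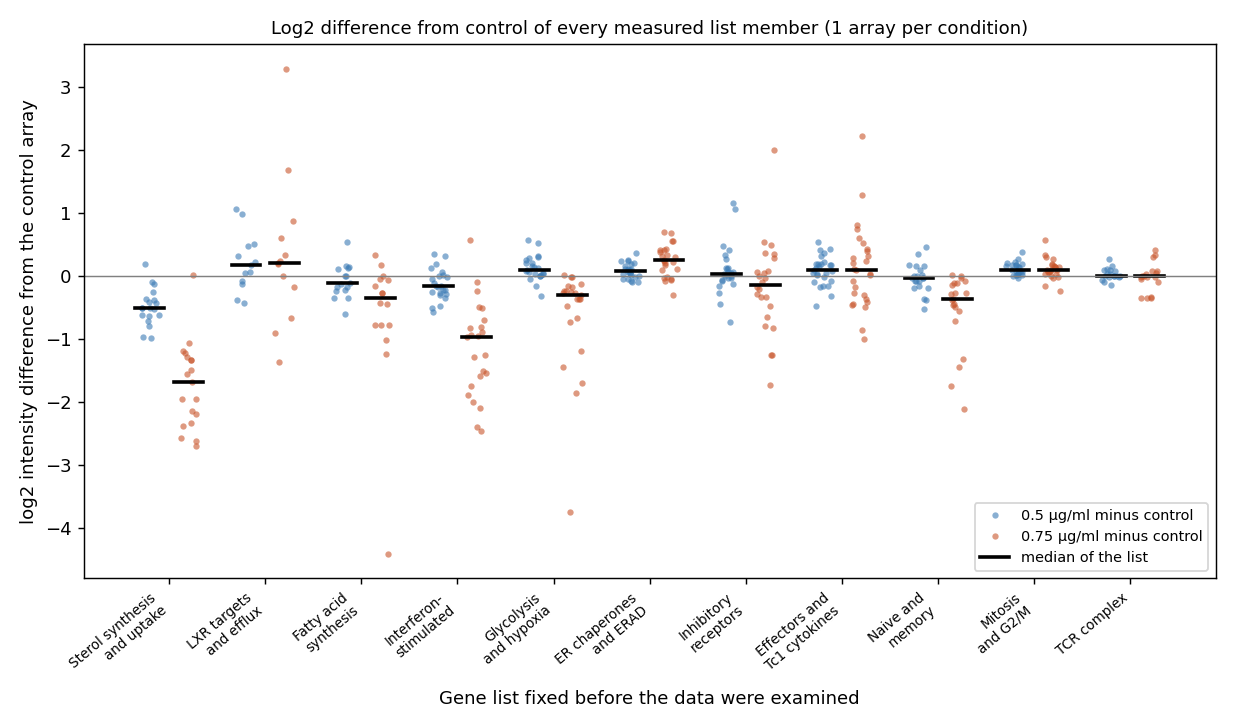
Log2 intensity difference from the control array (vertical axis) of every measured member of 11 gene lists (horizontal axis), at 0.5 µg/ml (blue) and 0.75 µg/ml (orange) cholesterol, with 1 point per gene and a black bar at each list's median. The sterol synthesis medians lie at -0.51 and -1.68, and the interferon-stimulated medians at -0.16 and -0.97.

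The third comparison set the 2 doses side by side. Sterol synthesis genes were lower at 0.75 than at 0.5 µg/ml by a median of -1.17, with 12 of 19 at least 2-fold lower, among them Hmgcs1 (-2.19), Fdps (at least 2.82-fold lower) and Sqle (at least 2.43-fold lower). Interferon-stimulated genes were lower by a median of -1.01, or -0.27 with values under 102 raised to that level, and hypoxia and glycolysis genes by -0.50, and both lists, like the sterol list and the naive and memory list (-0.29), lay below all random lists. Between the doses 44 genes were at least 2-fold higher at 0.75 µg/ml and 130 lower. Against the background level, Fads2 was at least 9.98-fold and Aldoc at least 5.45-fold lower, while Rai14 was at least 3.16-fold, Sulf2 at least 3.11-fold and Abca1 at least 1.60-fold higher. Chaperones of the endoplasmic reticulum were higher by 0.17, above all random lists, and p53 targets (0.15) and type 2, type 9 and type 17 genes (0.14, or 0.00 with dim values raised) lay above the middle 95%, while fatty acid synthesis genes (-0.21), inhibitory receptors (-0.19, or -0.07 with dim values raised), ribosomal protein genes (-0.17) and ATF4 and CHOP targets (-0.13, or -0.07 likewise) were lower, each under the 2.5th percentile. The LXR targets (0.08) and the effectors and Tc1 cytokines (0.07, or 0.00 with dim values raised) lay within the middle 95%.

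Of the 172 genes lower at 0.75 µg/ml, 140 (81.4%) were below the control at 0.5 µg/ml, with a median difference of -0.25 against -1.36. Of the 39 higher genes 28 (71.8%) were above it, with medians of 0.30 and 1.26. Simulated arrays without an effect that share the control gave 95.8% and 95.7% with noise taken from the difference between the doses. With the smaller noise of the 0.5 µg/ml comparison they gave 96.5% and 98.6%. The simulated arrays hold no effect at 0.75 µg/ml, so they do not give the share that an effect at that dose alone would bring. The observed shares therefore do not decide whether the doses have an effect in common. By measured values, 2 genes, Abcg1 and Havcr2, were at least 2-fold higher at both doses and 4, Tgm2, Fscn1, Galc and Papss2, at least 2-fold lower. Havcr2, Fscn1, Galc and Papss2 were under the background level on every array, and with values under 102 raised to that level only Abcg1 and Tgm2 remained. Independent lists of these sizes would share 0.036 higher and 0.094 lower genes, and simulated arrays without an effect that share the control shared 1.15 and 1.2, or 0.03 and 0 with the smaller noise. The noise taken between doses includes their real differences, so it overstates chance. Part of the excess may come from the shared control array. Across genes, which are not independent replicates, the differences at both doses had a Pearson r of 0.48. Simulated arrays without an effect gave 0.50 with noise from either source. All simulated arrays had the same noise per level bin, which sets r near 0.50 whatever the size of the noise. The measured differences had unequal SDs, 0.21 at 0.5 µg/ml and 0.36 at 0.75 µg/ml. Setting 0.48 beside 0.50 therefore cannot show whether the doses share an effect. The covariance was 0.0357 against a simulated 0.0499 with noise taken between doses and 0.0221 with the smaller noise, an excess of 0.0136 over the latter. With 1 array per condition the noise itself was not measured, so whether the doses share an effect across all genes stays open. Ctla4 and Egln3 lay slightly above the control at 0.5 µg/ml, at 0.06 and 0.25, and below it at 0.75 µg/ml, at -1.73 and -1.44.

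**Figure D2:**
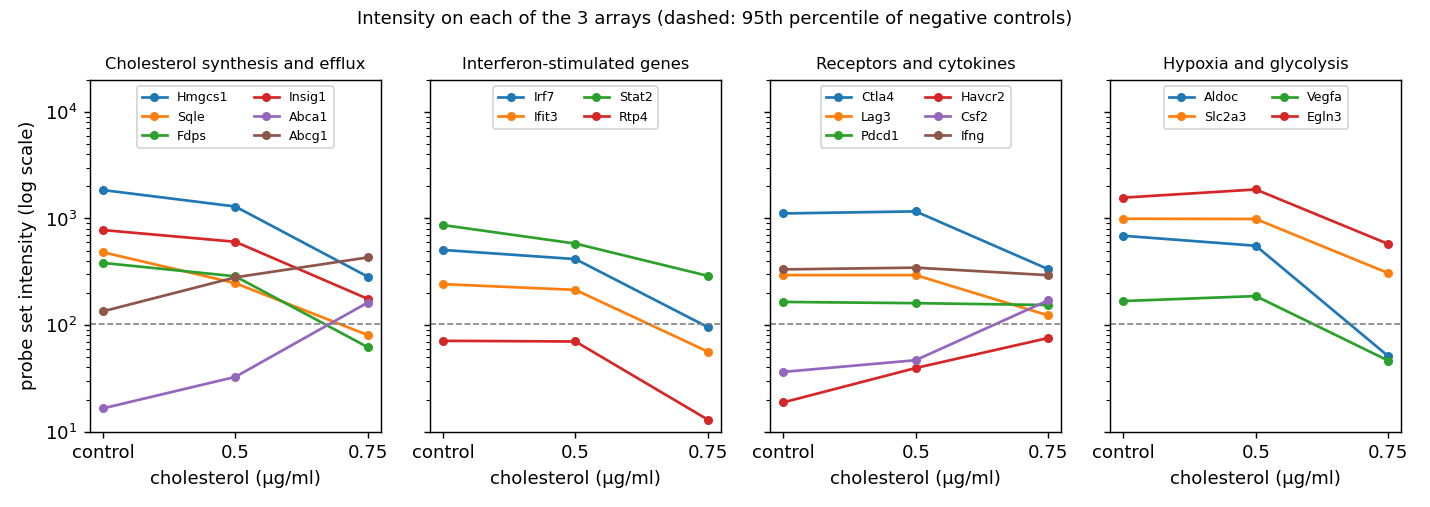
Probe set intensity (vertical axis, log scale) on the control array and at 0.5 and 0.75 µg/ml cholesterol (horizontal axis) for genes of 4 groups, with 1 line per gene and a dashed line at an intensity of 102, the highest 95th percentile of negative controls. Hmgcs1 lies at 1848, 1295 and 285 in order of dose, Abcg1 at 135, 280 and 431, and Ctla4 at 1115, 1166 and 335.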

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

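The test on positive-control probe sets was chosen after the result was seen, and the other tests in this part were set before theirs. Hypoxia and glycolysis genes differed in opposite directions at the 2 doses, with list medians of 0.090 at 0.5 µg/ml and -0.30 at 0.75 µg/ml, and 0.75 against 0.5 µg/ml gave -0.50, a difference that was not tested across replicates. Slc16a3, a lactate exporter chosen after its values were seen, followed this pattern with 0.29 and -1.19. After the trend with level was removed the median at 0.75 µg/ml was -0.34 (95% interval -0.71 to -0.24). Level-matched random lists share such a trend, and the middle 95% of their medians was already -0.07 to 0.13. The removal could therefore change little. Both results argue against a level-dependent normalization error as the whole cause. A list of 26 further hypoxia-inducible genes had medians of 0.13 and -0.46, and the second lay below all 10000 random lists, which goes with lower expression of hypoxia-inducible genes in general. Whether cholesterol or a difference in cell density or oxygen between the cultures may lie behind this stays open, since each condition has 1 array.

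Far more genes differed at least 2-fold at 0.75 than at 0.5 µg/ml, 211 against 16. A noisier array at 0.75 µg/ml would widen the control probe sets too, yet the SD over positive controls was 1.04 times that at 0.5 µg/ml (95% bootstrap interval 0.956 to 1.13), while the SD over genes was 1.70 times as large. After the trend with level was removed 211 genes differed at 0.75 µg/ml, which argues against that trend. The larger cholesterol dose may account for the difference, as a hypothesis, and a difference between cultures stays open as well.

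The p53 target list had medians of -0.15 at 0.5 µg/ml and 0.13 at 0.75 µg/ml, and 0.75 against 0.5 µg/ml gave 0.15, likewise not tested across replicates. Btbd35f20, a member of a family of near-identical gene copies whose signals cannot be assigned to 1 copy with certainty, differed by -1.09 and 0.89, also untested. Its intensities were 61.3 on the control array, 28.8 at 0.5 and 114 at 0.75 µg/ml, the first 2 under the background level of 102, and with the background floor the differences of Btbd35f20 were 0.00 and 0.16. Among 1229 transcript probe sets that pass the level filter and are unnamed here, 1 was at least 2-fold higher and 0 were lower than the control at 0.5 µg/ml, and 28 were higher and 19 lower at 0.75 µg/ml.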

How the results depend on the processing

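The background floor and the smaller simulation noise were chosen after the result was seen. Quantile normalization, median centring, removal of the trend with level and the mean of probe sets kept all 8 counts of genes within 1.5 times, and moved the median of all kept genes by less than 0.1. The deposited arrays already had near-identical distributions, so quantile normalization and median centring could change little. The mean of probe sets could matter for only the 55 genes with more than 1 probe set. The 15 medians of the main lists stayed within their 95% intervals under each setting run, and the spreads and the correlation within 1.5 times. Some intervals are wide, such as -0.67 to 0.87 for LXR targets at 0.75 µg/ml, so staying within them is a weak check. With the background floor the LXR medians were 0.00 at 0.5 and at 0.75 µg/ml against the control. At 0.75 µg/ml the inhibitory receptor median was then -0.02 and the effector and Tc1 cytokine median 0.00. Counts depended on the threshold and on how dim genes were treated. In the order higher and lower at 0.5 µg/ml, higher and lower at 0.75 µg/ml, higher and lower between doses, and higher and lower at both doses, a 1.5-fold threshold gave 103, 109, 277, 498, 197, 407, 42 and 48 genes, and the background floor 2, 1, 15, 98, 12, 75, 1 and 1. Without a level filter, 25 and 29 genes were higher and lower at 0.5 µg/ml, 82 were higher at 0.75 µg/ml, 76 were higher between doses, and 5 and 11 were higher and lower at both doses. Among only the brightest genes by level there were 2 and 1 at 0.5 µg/ml, 14 and 108 at 0.75 µg/ml, 14 higher between doses, and 1 and 1 at both doses. The B cell marker list at 0.75 µg/ml changed sign, from -0.18 to 0.080, when only members past the filter were used. The cause was not tested. Among the other list medians 8 moved outside their interval, all of lists of interferon-stimulated genes (-0.49 at 0.75 µg/ml and -0.27 between doses with the floor), the T cell receptor complex, or markers of myeloid cells. Under the background floor 40 single-gene differences moved and 281 stayed. Matching random lists on the control array changed 2 list calls to higher, DNA replication at 0.75 µg/ml and NRF2 targets between doses, and left 82. No probe set had several gene symbols, so keeping such probe sets gave no further value. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Signal over background limits Havcr2, Fscn1, Il9 and most markers of other cell types.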

Other observations

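The test on macrophage, dendritic cell and monocyte markers was chosen after the result was seen, and the other tests in this part were set before theirs. Lists of further interferon-responsive genes, outside those fixed at the start, were also low. The 29 further type I interferon-stimulated genes had medians of -0.14 at 0.5 µg/ml and -0.69 at 0.75 µg/ml (95% interval -0.94 to -0.43), and 28 of them were below the control at the higher dose. The members named next were chosen after their values were seen. Xaf1, an apoptosis-linked interferon target, was at 119 against 402, and Ifih1, which encodes a sensor of viral RNA, was at 206 against 463. The exception was Ifitm3, at 387 against 195. The 24 further interferon-gamma-inducible genes, mostly of antigen processing, had medians of -0.15 and -0.22 (95% interval -0.39 to -0.10), with Tap1 at 1777 against 2288 and the immunoproteasome gene Psmb9 at 1047 against 1587. Both lists lay below all 10000 random lists at both doses.

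Interferon-stimulated genes at 0.75 µg/ml had a median of -0.98 (95% interval -1.61 to -0.83) once the trend with level was removed. Level-matched random lists share such a trend, and the middle 95% of their medians was already -0.10 to 0.13. The removal could therefore change little. Both results argue against a level-dependent normalization error as the cause. The median of -0.69 in the further type I list argues against the choice of members as the cause. The median of -0.22 in the interferon-gamma list goes with a lower interferon-gamma response, which may contribute. The type I list had the lower median, but both intervals are over members on 1 pair of arrays. They do not rank the type I and interferon-gamma responses. Loss of macrophages, dendritic cells or monocytes from the culture stays open. Their median marker lay 0.54 log2 above the median negative control on the control array (95% interval -0.10 to 1.43). Lyz2, Tyrobp and Fcer1g, abundant in such cells and chosen after their values were seen, were at 12.9, 22.0 and 21.7. However, H2-Ab1 was lower together with the interferon-stimulated genes, and the markers past the level filter had a median of -0.41 at 0.75 µg/ml. Another class II marker, H2-Eb1, was at 153 on the control array, 103 at 0.5 and 99.1 at 0.75 µg/ml, so it was already lower at 0.5 µg/ml. Of all 18 measured markers, 9 were above and 9 below the control at 0.75 µg/ml.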
